A study of Caenorhabditis elegans with 4 samples.

How the data were processed

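Gene expression was measured by RNA sequencing in 4 samples of young adult *Caenorhabditis elegans*, a nematode worm. Per the labels, 2 samples were gonads dissected from N2, the standard wild-type laboratory strain, and 2 were whole worms of the *glp-4(bn2)* mutant. This temperature-sensitive allele is widely used because mutants raised at the restrictive temperature make very few germ cells while keeping their somatic tissues. The labels give no growth temperature. Per the labels' protocols, total RNA was extracted with a kit for small amounts of material, ribosomal RNA was removed with a bead-based kit, and libraries were made with a cDNA amplification kit (Ovation RNA-Seq V2). Nothing in the labels states that strand was kept, so reads from a gene and from an overlapping gene on the opposite strand could not be told apart. Amplified reads without molecular identifiers are not independent molecules, and the counting intervals given here cover counting error only.

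The deposited raw count table holds whole-number counts per gene under WormBase gene identifiers, and the aligner, the counting program and the genome build are not given in the sources used here. The authors also deposited a normalized table on a log2 scale. Its values equalled log2 of the count scaled to the mean library total plus 8, within 5e-05, so that a count of 0 is listed at 3. Both tables have 20182 rows in the same order. One row was left out because its 4 counts repeated those of *pat-10* under a second name, which left 20181 rows. Of these, 19513 matched a gene of the Ensembl release 115 annotation of the WBcel235 assembly by identifier, and 18778 had a gene name there. The other 668 rows kept their identifiers and held between 1.14% and 1.22% of the counts of a library. Coordinates and chromosomes come from that annotation, which may not be the one the authors used. Among the matched rows, 18772 were protein coding and 720 were pseudogenes, and 2383 rows of the table had a count of 0 in every library. No row lay on mitochondrial DNA, so the list of mitochondrially encoded genes had 0 members and gave no result.

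Library totals were 21806767 and 24148583 counts for gonad replicates 1 and 2, and 19538620 and 25624824 counts for *glp-4* whole-worm replicates 1 and 2. A count of 3, the upper limit that a count of 0 allows, corresponds to between 0.117 and 0.154 CPM (counts per 1e+06 counts of the library) in a single library. Replicates were compared before they were treated as such. A chi-square test of the counts gave 20.9 per degree of freedom between the gonad libraries and 18.1 between the whole-worm libraries, so neither pair agreed within sampling noise and each library was counted separately.

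Raw counts were tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3 (robust fit, group as the only term), after TMM normalization and the default filterByExpr filter (minimum count 10, minimum total 15). P-values were adjusted by the Benjamini-Hochberg method. A gene was called enriched at an adjusted p under 0.05 and a fold of at least 2. It was called specific when it was enriched, had at least 5 CPM in both libraries of its own group and had under 1 CPM in both libraries of the other, on TMM-adjusted CPM. Log2 fold changes are gonad minus *glp-4* whole worm, and their standard errors (SE) were obtained from the F statistic. Where a group had 0 counts in both libraries, the fitted fold depends on a prior count, so list medians were also computed with such genes at a bound, set from 3 counts over the group. On simulated counts with the means, library sizes and dispersions of these libraries (3 sets, 200 changed genes each, 12642 to 12654 genes tested), the same test recovered 75.4% of genes changed 2-fold, 96.2% of those changed 4-fold and 100% of those changed 8-fold. False calls made up 8.1% of its calls there, above the nominal 5%. In the data themselves 12183 of 13101 tested genes differed, many by more than 8-fold. These rates therefore hold for a comparison with few changed genes and do not carry over to this one.

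Lists of genes for germline, gamete, somatic and housekeeping functions were fixed before the data were examined, as were the definitions of enriched and specific genes, the test of X linkage and the rule for named genes. Each list was tested with camera (limma 3.58.1, preset correlation 0.01) on the edgeR data, adjusted over the 21 lists with tested members, and again with an estimated correlation and with fry. Camera compares a list with the other tested genes and not with no change. Of all 13101 tested genes 6952 were soma-enriched, and the median log2 fold change was -1.50. A list with mostly soma-enriched members can therefore fail this test. The estimated correlation rested on 2 residual degrees of freedom, too few to decide for or against a list. X linkage was tested with two-sided Fisher's exact tests, 4 in the family. Named genes were the 8 gonad-enriched and the 8 soma-enriched genes with a name, a log2 fold of at least 3 and no overlap between groups that had the highest mean CPM in their own group. To these were added, per list, the 3 tested members with the highest mean CPM, the 1 enriched member with the highest mean CPM that went against most of its list, and *glp-4*. A gene of the somatic gonad list that the rule selected is not described in the text. Genes named outside this rule were chosen after their values were seen, also where the text does not mark them.

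The alternatives tried were RLE, upper-quartile and library-size scaling, no low-count filter and a stricter one (5 CPM in both libraries of a group), DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library in turn, adjusted p under 0.01, no fold minimum, a fold of at least 4, glmTreat against a fold of 2, detection limits of 0.5 and 2 CPM, an own-group minimum of 2 CPM, and limma on the authors' normalized table as deposited, which was already on a log2 scale. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the remaining tables and plots.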

Results

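RNA was sequenced from dissected gonads of wild-type young adult *C. elegans* (2 libraries) and from whole young adults of the germline-deficient *glp-4(bn2)* mutant (2 libraries). The series set out to define transcripts that are specific to or enriched in the germline and the soma, and the comparison of these groups addresses that question. A dissected gonad holds germ cells from the mitotic zone to oocytes together with the somatic sheath, and a *glp-4* worm holds the somatic tissues, the somatic gonad among them. Totals ranged from 19538620 to 25624824 counts per library. Gonad libraries had counts for 12796 and 12550 genes, and whole-worm libraries for 16177 and 16231. Across genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.998 between the gonad libraries, 0.994 between the whole-worm libraries and 0.463 to 0.468 between groups. The labels do not say that the duplicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The mutated gene *glp-4* itself, which encodes a valyl-tRNA synthetase (WBGene00006936, chromosome I, 13548074 to 13559361), had 396 and 433 CPM in the gonad libraries and 570 and 606 CPM in the whole worms. The RNA level does not check a mutation that changes the protein sequence.

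Among gonad-enriched genes with a log2 fold of at least 3, the most abundant encoded mostly eggshell proteins and germline RNA regulators, while the most abundant gene of either gonad library was the chaperone gene *hsp-90* (1.47% and 1.52% of counts). First by the naming rule was *cbd-1*, which encodes a chitin-binding eggshell protein (WBGene00010351, chromosome IV, 11372991 to 11377627). It had 12531 ± 387 CPM (SD, n = 2) in gonads against 133 ± 13.7 CPM in whole worms, a log2 fold change of 6.55 ± 0.22 (SE). The eggshell chondroitin proteoglycan genes *cpg-2* (WBGene00015102, chromosome III, 7102092 to 7103990) and *cpg-1* (WBGene00000465, chromosome III, 4489359 to 4491392) followed at 7922 ± 281 and 6213 ± 63.4 CPM (SD, n = 2), 135-fold and 157-fold above whole worms. The germ granule helicase gene *cgh-1* (WBGene00000479, chromosome III, 7495320 to 7497832) reached 4082 ± 483 CPM in gonads but also 466 ± 61.5 CPM in whole worms, a log2 fold change of 3.13 ± 0.18. The lectin-domain gene *clec-87* (WBGene00007709, chromosome I, 10184462 to 10185520) was higher in gonads by 6.44 ± 0.20 on the log2 scale, with 14.4% of its exon length shared with *iars-2* on the opposite strand.

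The other 3 genes of this set were also RNA regulators. The Y-box protein gene *cey-2* (WBGene00000473, chromosome I, 5619569 to 5620669) had the steepest difference of the 8, with a log2 fold change of 8.52 ± 0.24 and 3489 ± 349 CPM (SD, n = 2) in gonads. The nuclear Argonaute gene *hrde-1* (WBGene00007624, chromosome III, 4172337 to 4176159) had 3076 ± 509 CPM in gonads and 27.4 ± 1.47 CPM in whole worms. The PUF-family gene *puf-5*, which acts in oogenesis (WBGene00004241, chromosome II, 8575541 to 8577787), had 2598 ± 78.6 CPM in gonads and 14.8 ± 1.61 CPM in whole worms. Across these 8 genes the largest adjusted p was 1.21e-12, for *cgh-1* (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

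Among soma-enriched genes with a difference of at least the same size, the most abundant encoded mostly yolk and muscle proteins. The vitellogenin gene *vit-6* (WBGene00006930, chromosome IV, 8261157 to 8266459), whose yolk product is made in the intestine, had 20181 ± 2764 CPM (SD, n = 2) in whole worms and 91.9 ± 17.4 CPM in gonads. Its log2 fold change was -7.78 ± 0.26 (SE). Values for *vit-2* (WBGene00006926, chromosome X, 5101042 to 5106169) and *vit-1* (WBGene00006925, chromosome X, 7727889 to 7733168) were 15090 ± 2374 and 7888 ± 1411 CPM in whole worms, 244-fold and 242-fold above gonads. The body wall muscle myosin gene *unc-54* (WBGene00006789, chromosome I, 14855901 to 14863482) had 5449 ± 394 CPM against 59.2 ± 7.16 CPM. The muscle troponin T gene *mup-2* (WBGene00003495, chromosome X, 6408471 to 6410227) had 3469 ± 318 CPM against 92.7 ± 13.3 CPM.

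Genes of muscle, of metabolism and of unknown function completed the set. The calponin-like gene *clik-1* (WBGene00020808, chromosome V, 6765768 to 6768732) was 142-fold higher in whole worms, with 13.4% of its exon length shared with a gene on the opposite strand. The gene *pud-3* (WBGene00017501, chromosome V, 2324634 to 2325152) had 4257 ± 11.4 CPM (SD, n = 2) in whole worms and 2.37 ± 1.27 CPM in gonads, a log2 fold change of -10.80 ± 0.30, or -11.48 without gonad replicate 2. The aldehyde dehydrogenase gene *alh-8* (WBGene00000114, chromosome II, 11729055 to 11731198) differed by -4.17 ± 0.18 (SE) on the log2 scale and kept 193 ± 0.077 CPM in gonads. The largest adjusted p of the 8 was 1.26e-14, for *alh-8* (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

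Of 13101 genes tested, 12183 differed at an adjusted p under 0.05, 4772 higher in gonads and 7411 higher in whole worms. With a fold of at least 2, 4043 genes were gonad-enriched and 6952 were soma-enriched. Soma-enriched genes differed more steeply, by a median of 54.3-fold against 5.42-fold for gonad-enriched genes. Because 1582 soma-enriched genes had a count of 0 in both gonad libraries, their median with those genes at the bound was 26.9-fold. At that bound 3205 soma-enriched genes (46.1%) and 722 gonad-enriched genes (17.9%) differed by at least 32-fold.

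The strict definition left 294 gonad-specific and 2259 soma-specific genes. Ranked by level after the data were examined, *mex-1*, which encodes a zinc-finger RNA-binding protein of oocytes and embryos, led the gonad-specific genes with 356 CPM in gonads and 0.772 CPM in whole worms. It was followed by *skpt-1* (208 CPM against 0.787 CPM). Gonad-specific genes of the lists included the stem cell regulators *fbf-1* and *sygl-1*, the meiotic nuclease gene *spo-11*, the egg activation genes *egg-4* and *egg-5* and the germ granule genes *meg-2* and *meg-4*. The most abundant soma-specific genes were *irg-7*, an immune response gene (2291 CPM in whole worms against 0.694 CPM in gonads), and *swt-3* (1543 against 0.499 CPM). The fatty acid desaturase gene *fat-6* (701 against 0.807 CPM) and the glyoxylate cycle gene *icl-1* (761 against 0.802 CPM) were among them as well. The gonad-specific count depended on the detection limit, at 181 genes with a limit of 0.5 CPM and 482 with 2 CPM.

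**Figure D1:**
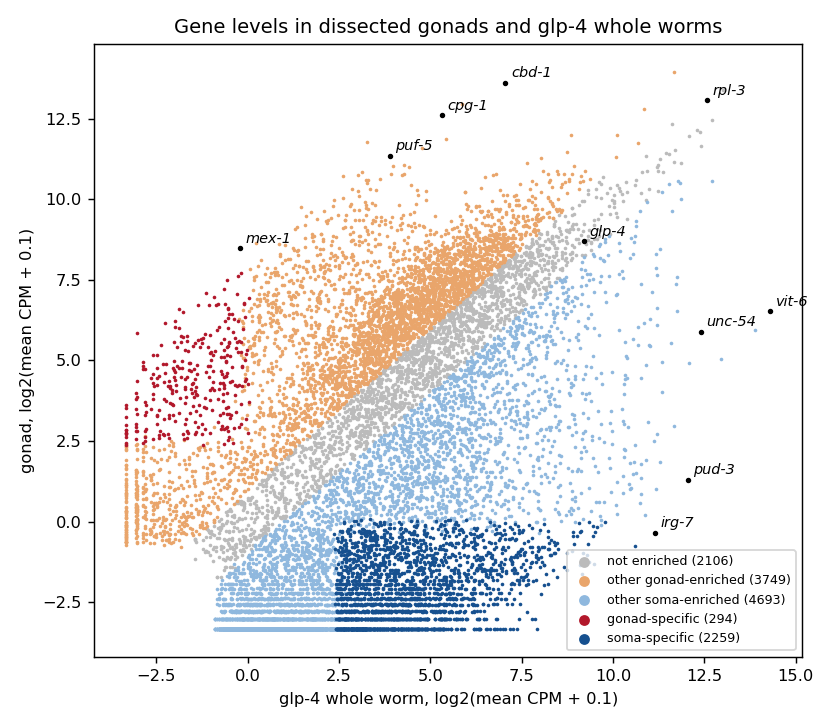
Mean TMM-adjusted CPM of each tested gene in *glp-4* whole worms (x axis) and gonads (y axis), both as log2(mean CPM + 0.1) over 2 libraries per group, coloured by class. The 294 gonad-specific and 2259 soma-specific genes lie along the edges, with *cbd-1* near the top and *vit-6* at the far right.

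Genes for meiosis and for germline stem cells were mostly higher in gonads. All 30 tested meiosis and synaptonemal complex genes were gonad-enriched, with a median log2 fold change of 6.09 (camera adjusted p = 1.1e-12; adjusted p = 0.171 with an estimated correlation). Among them the meiotic cohesin gene *rec-8* had 392 ± 22.1 CPM (SD, n = 2) in gonads and 7.60 ± 0.14 CPM in whole worms, and the polo-like kinase gene *plk-2* differed by 5.38 ± 0.16 (SE) on the log2 scale. The gene *him-17*, which is needed for meiotic double-strand breaks, differed less, by 2.09 ± 0.13, with 74.4 ± 0.095 CPM in whole worms. Of 14 stem cell and mitotic zone genes, 12 were gonad-enriched, with a median of 4.04 (camera adjusted p = 1.67e-06; adjusted p = 0.171 with an estimated correlation). The translational regulator genes *gld-3* (7.47 ± 0.21), *gld-1* (6.97 ± 0.20) and *puf-8* (6.58 ± 0.21) were its most abundant members, while *gld-2* and *atx-2* stayed under a 2-fold difference.

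Germ granule and small RNA genes were mostly higher in gonads as well. All 13 P granule genes were gonad-enriched, with a median log2 fold change of 5.55 (camera adjusted p = 4.44e-07; adjusted p = 0.171 with an estimated correlation). Beside *cgh-1*, the Vasa-like helicase gene *glh-1* was higher in gonads by 4.32 ± 0.16 and *car-1*, which encodes an Sm-like RNA-binding protein, by 3.46 ± 0.18 (SE) on the log2 scale. Of 21 tested small RNA pathway genes, 19 were gonad-enriched, with a median of 3.24 (camera adjusted p = 4.5e-08; adjusted p = 0.171 with an estimated correlation). The most abundant after *hrde-1* were the Argonaute genes *prg-1* (891 ± 31.2 CPM in gonads, SD, n = 2, and 80.5 ± 7.11 CPM in whole worms) and *csr-1* (826 ± 69.0 against 121 ± 1.38 CPM). The remaining *alg-3* and *rde-12* were not enriched in either direction.

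Female gamete genes were strongly represented in gonads and many sperm genes had few counts in either group. All 29 oocyte and eggshell genes were gonad-enriched, with the highest median of the lists at 6.88 (camera adjusted p = 1.1e-12; adjusted p = 0.171 with an estimated correlation). Of 25 spermatogenesis genes, 13 had enough counts to be tested, of which 8 were gonad-enriched and 3 soma-enriched. Their median of 2.12 (1.52 without gonad replicate 1) did not pass the test (camera adjusted p = 0.0674; adjusted p = 0.289 with an estimated correlation). The most abundant were regulators rather than sperm structural genes, namely *fog-1* (118 ± 15.8 CPM in gonads, SD, n = 2) and *cpb-1* (105 ± 11.9 CPM), which encode RNA-binding proteins of the CPEB family, and the transcription factor gene *spe-44* (61.6 ± 4.94 CPM), whose log2 fold change of 5.69 ± 0.28 became 5.09 without whole-worm replicate 1 and 6.88 without whole-worm replicate 2. Against the list, *swm-1*, a secreted inhibitor of sperm activation, had 2 counts in gonads and 623 in whole worms, a ratio of 317 with an exact counting interval from 87.4 to 2623 (fitted log2 -11.21 without gonad replicate 1 and -6.98 without gonad replicate 2). The spermatogenesis genes *spe-4* and *spe-26*, named after their values were seen, were soma-enriched as well, at low levels. They had 0.188 and 0.760 CPM in gonads and 3.18 and 6.58 CPM in whole worms. The 30 major sperm protein rows summed to 40 and 11 counts in gonads and to 5 and 2 in whole worms, and 0 passed the count filter. These genes are near-identical copies, whose reads can be lost or split between them in counting, so their levels are uncertain.

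Cell cycle and chromatin genes were also higher in gonads. All 26 DNA replication and cell cycle genes were gonad-enriched, with a median log2 fold change of 5.63 (camera adjusted p = 4.63e-12; adjusted p = 0.171 with an estimated correlation). They were led by the cyclin gene *cyb-3* (1766 ± 228 CPM in gonads, SD, n = 2), the replicative helicase gene *mcm-7* (1244 ± 228 CPM) and the PCNA gene *pcn-1* (1223 ± 23.2 CPM), which had 19.4, 24.9 and 29.6 CPM in whole worms. Of 19 germline chromatin regulators, 17 were gonad-enriched, with a median of 3.05 (camera adjusted p = 2.08e-07; adjusted p = 0.171 with an estimated correlation). Differences were 5.05 ± 0.17 for the histone methyltransferase gene *mes-4*, 3.93 ± 0.14 for the histone chaperone gene *lin-53* and 2.35 ± 0.15 for the methyltransferase gene *met-1*. The HP1-family gene *hpl-1* went the other way, by -1.47 ± 0.35, at 1.27 ± 0.217 CPM in gonads and 3.55 ± 1.20 CPM in whole worms.

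Histone genes split by copy. Of 70 rows, 43 had a count of 0 in every library and 23 were tested, of which 17 were gonad-enriched and 6 soma-enriched (median 3.22, camera adjusted p = 0.00140; adjusted p = 0.454 with an estimated correlation). The most abundant copies, *his-61* (1724 ± 7.55 CPM in gonads, SD, n = 2), *his-68* (1672 ± 32.1 CPM) and *his-62* (651 ± 142 CPM), had under 10 CPM in whole worms, whereas *his-41* was 36.2-fold higher in whole worms. Many copies are near-identical, so the values of single copies are uncertain, and *his-41* shares 33.6% of its exon length with another gene. The list's name pattern also took in genes that are not replication-dependent. Of the histone H3.3 genes, named after their values were seen, *his-74* (7.22 ± 0.19) and *his-72* (2.08 ± 0.15) were gonad-enriched and *his-71* (-4.33 ± 0.21) soma-enriched.

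Transcripts of genes on the germline lists were not absent from whole worms. Among members with at least 100 CPM in gonads, the whole-worm level was a median of 0.849% of the gonad level for 27 oocyte and eggshell genes, 1.38% for 17 meiosis genes and 1.87% for 24 cell cycle genes. It was 2.48% for 9 P granule genes, 10.6% for 13 small RNA pathway genes, 11.9% for 11 stem cell and mitotic zone genes and 12.1% for 15 chromatin regulators.

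Markers of the main somatic tissues were higher in whole worms. All 25 tested intestine genes were soma-enriched, with a median log2 fold change of -9.46, or -9.13 with the 1 gene at 0 in both gonad libraries at its bound (camera adjusted p = 6.5e-07; adjusted p = 0.171 with an estimated correlation). The aspartic protease genes *asp-1* (2371 ± 114 CPM in whole worms, SD, n = 2) and *asp-5* (1448 ± 190 CPM) and the microvillar actin gene *act-5* (1510 ± 78.7 CPM) had 6.46, 1.98 and 2.68 CPM in gonads. All 6 vitellogenin genes were soma-enriched, with a median of -7.91 (camera adjusted p = 0.00852; adjusted p = 0.454 with an estimated correlation), and some of them are near-identical copies whose single values are uncertain. All 14 pharynx genes were soma-enriched, with a median of -8.51, or -6.75 with 5 genes at their bound (camera adjusted p = 0.00148; adjusted p = 0.246 with an estimated correlation). The pharyngeal myosin genes *myo-1* and *myo-2* had 335 and 252 CPM in whole worms and 0.414 and 0.460 CPM in gonads, while the troponin I gene *tni-4* kept 18.7 ± 0.964 CPM in gonads.

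Muscle and neuron genes had the same direction with a few exceptions. Of 31 body wall muscle genes, 29 were soma-enriched, with a median log2 fold change of -5.37 (camera adjusted p = 4.17e-06; adjusted p = 0.300 with an estimated correlation). Beside *unc-54* and *mup-2*, the calponin-like gene *unc-87* had 2620 ± 394 CPM (SD, n = 2) in whole worms and 31.2 ± 0.354 CPM in gonads. The chaperone gene *unc-45* and the actin-depolymerizing factor gene *unc-60* were not enriched. Of 37 neuron genes, 35 were soma-enriched, with a median of -6.14, or -4.92 with 5 genes at their bound and -5.43 without gonad replicate 2 (camera adjusted p = 6.97e-06; adjusted p = 0.246 with an estimated correlation). The synaptic release genes *unc-18* and *unc-13* differed by -2.85 ± 0.14 and -4.92 ± 0.17 (SE), and the synaptobrevin gene *snb-1* by -0.71 ± 0.13, under the fold minimum. The pan-neuronal gene *unc-119* had an adjusted p of 0.0776 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

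Genes of the body surface and of defence followed. Of 174 cuticle collagen genes in the count table, all that could be tested but 4 were soma-enriched, with a median of -8.13, or -7.17 with 54 genes at their bound (camera adjusted p = 4.63e-12; adjusted p = 0.171 with an estimated correlation). The most abundant were *col-124* (2582 ± 461 CPM in whole worms, SD, n = 2), *col-129* (1537 ± 170 CPM) and *col-80* (1001 ± 74.4 CPM). Of 16 epidermis genes 13 were soma-enriched, among them the spectraplakin gene *vab-10* (-2.27 ± 0.15) and the apical junction gene *ajm-1* (-3.86 ± 0.15), but the list did not pass (median -3.55, camera adjusted p = 0.0596; adjusted p = 0.604 with an estimated correlation). The transcription factor genes *lin-26* (1.51 ± 0.14) and *nhr-23* (4.06 ± 0.16) of that list were gonad-enriched. Of 146 tested innate immunity and antimicrobial genes, 138 were soma-enriched, with a median of -8.05, or -6.32 with 56 genes at their bound (camera adjusted p = 3.55e-09; adjusted p = 0.171 with an estimated correlation). They included *irg-7* (-11.69 ± 0.26) and *clec-63* (-10.24 ± 0.25). All 6 gonad-enriched members encode lectin-domain proteins, with *clec-87* the most abundant, followed by *clec-91* (900 ± 44.1 CPM in gonads) and *clec-88* (672 ± 22.6 CPM).

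The share of the whole-worm level that remained in gonads differed by tissue. Among members with at least 100 CPM in whole worms, the gonad level was a median of 2.10% for 23 body wall muscle genes and 0.137% for 17 intestine genes. It was 0.415% for 6 vitellogenin genes, 0.513% for 29 cuticle collagen genes, 0.118% for 16 innate immunity genes, 0.330% for 4 pharynx genes and 3.03% for 4 neuron genes.

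Lists of cells found in or near both samples had members in both directions. Mixed directions are not particular to these lists, as 4043 of all 13101 tested genes were gonad-enriched and 6952 soma-enriched. Of 17 somatic gonad genes, 4 were gonad-enriched and 9 soma-enriched (median -1.48, camera adjusted p = 0.745; adjusted p = 0.875 with an estimated correlation). Among the former, named after their values were seen, were the Notch ligand gene *apx-1* (5.50 ± 0.25) and the innexin gene *inx-8* (1.35 ± 0.15). For *apx-1* the levels were 46.4 CPM in gonads and 1.04 CPM in whole worms, although *glp-4* worms hold a somatic gonad as well. Dissected gonads also contain germ cells, so gonad enrichment does not assign these transcripts to somatic gonad cells. The IP3 receptor gene *itr-1* was 23.5-fold higher in whole worms. The filamin gene *fln-1* had a log2 fold change of 0.34 ± 0.14 (SE), which became -0.02 with upper-quartile scaling. Of 5 coelomocyte genes, the endocytosis gene *cup-5* was gonad-enriched (2.04 ± 0.13) and 3 were soma-enriched, among them the channel-family gene *cup-4* (-5.08 ± 0.40). For this list the median was -3.96 (-2.98 without gonad replicate 1). Camera, which compares it with the other tested genes and not with no change, gave the direction up (camera adjusted p = 0.967, or adjusted p = 0.970 with an estimated correlation). The fifth gene, *rme-8*, had 720 ± 86.5 CPM (SD, n = 2) in gonads and 409 ± 21.6 CPM in whole worms.

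Housekeeping and stress genes divided by member. Of 73 cytosolic ribosomal protein genes 67 were not enriched (median -0.12, camera adjusted p = 0.405, or adjusted p = 0.875 with an estimated correlation). Camera gave the direction up, and the list median lay above the median of -1.50 of all tested genes. The abundant *rpl-3*, *rps-1* and *rpl-6* differed by 0.48 ± 0.18, -0.30 ± 0.17 and -0.16 ± 0.18 (SE). The exceptions, named after their values were seen, included paralog pairs that went opposite ways. The gene *rpl-11.1* had 633 CPM in gonads and 14.8 CPM in whole worms (5.42 ± 0.18), and *rpl-11.2* had 15.6 and 1263 CPM (-6.34 ± 0.20). Likewise *rpl-25.2* was gonad-enriched (1.51 ± 0.15) and *rpl-25.1* soma-enriched (-4.97 ± 0.24), directions that held under every scaling tried. The genes *rpl-4* (1.06 ± 0.17) and *rps-23* (158 ± 25.6 CPM in gonads and 317 ± 5.31 CPM in whole worms) lay at the fold minimum, and each was under a 2-fold difference in some settings.

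Of 16 tested heat shock and stress genes, 12 were soma-enriched and 3 gonad-enriched (median -4.80, or -4.15 without gonad replicate 1, camera adjusted p = 0.136; adjusted p = 0.429 with an estimated correlation). The gonad-enriched members were chaperone genes, the cytosolic *hsp-1* (7049 ± 635 CPM in gonads, SD, n = 2, and 1830 ± 311 CPM in whole worms), the mitochondrial *hsp-6* (3.41-fold) and the endoplasmic reticulum *hsp-4* (5.67-fold). A second endoplasmic reticulum chaperone gene, *hsp-3*, was 3.77-fold higher in whole worms. The list matched 22 of its 23 names and did not hold *hsp-90*, the most abundant gene of the gonad libraries. Of 17 tested genes with the prefix *hsp*, counted after the results were seen, 6 were gonad-enriched and 10 soma-enriched. These shares of 35.3% and 58.8% lay near the 30.9% and 53.1% of all other tested genes. For each of the 21 lists the counts of enriched members adjusted over the list alone were the same as those adjusted over all genes. Of the lists named here, those for body wall muscle, pharynx, epidermis and cuticle collagens shared 1 gene each with another list, and those for intestine and innate immunity shared 2.

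**Figure D2:**
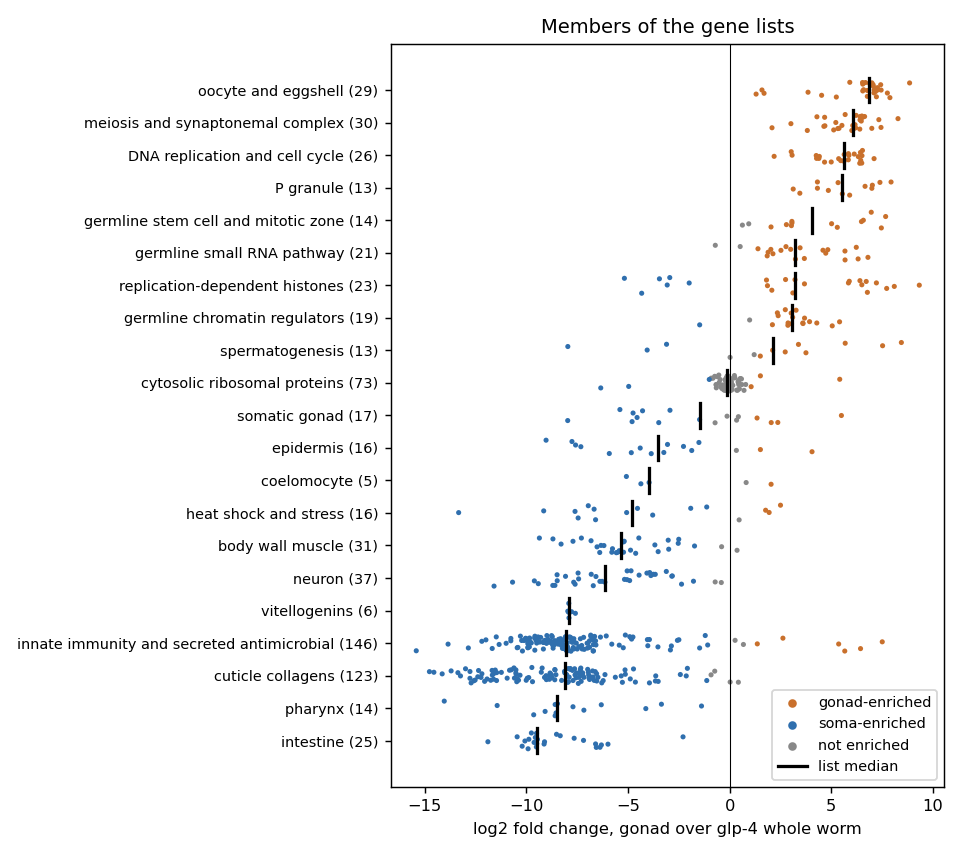
Log2 fold change (gonad over *glp-4* whole worm, x axis) of each tested member of the 21 lists, with the number tested in brackets, coloured by call, and the list median as a bar. Medians run from 6.88 for oocyte and eggshell genes to -9.46 for intestine genes, and ribosomal protein genes cluster near 0. Fitted values of genes at 0 in a group are not bounds, and *fln-1* of the somatic gonad list changes sign with upper-quartile scaling.

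The X chromosome, which is largely silenced in much of the *C. elegans* germline, was poor in gonad-enriched genes. Of 3927 gonad-enriched genes with a chromosome, 152 (3.87%) were X-linked, against 1814 of the 8817 other tested genes (20.6%), an odds ratio of 0.155 (95% interval 0.130 to 0.184, Fisher's exact test, adjusted p = 3.10e-156). Soma-enriched genes were X-linked in 1570 of 6773 cases (23.2%), with an odds ratio of 4.25 (3.78 to 4.79, adjusted p = 3.10e-156). By chromosome, 7.73% of tested X genes were gonad-enriched, against 23.1% on chromosome V and 44.4% on chromosome I. The depletion was not detected among gonad-specific genes, of which 39 of 285 (13.7%) were X-linked (odds ratio 0.867, 0.599 to 1.22, Fisher's exact test, adjusted p = 0.456). Soma-specific genes were X-linked in 472 of 2206 cases (21.4%, odds ratio 1.65, 1.47 to 1.85, adjusted p = 2.41e-16).

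**Figure D3:**
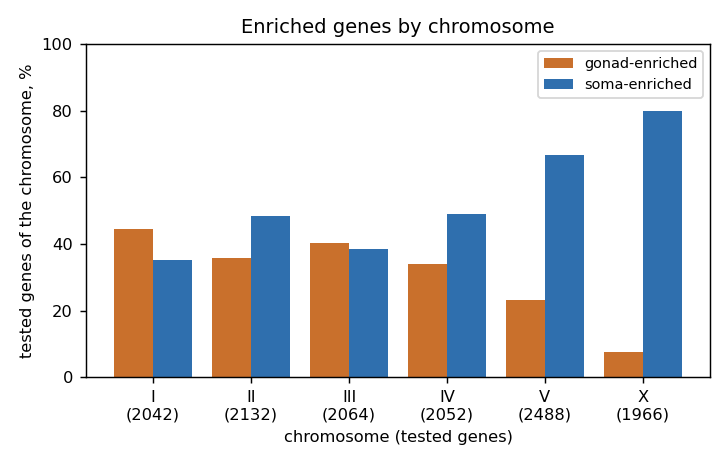
Percentage of the tested genes of each chromosome (x axis, number tested in brackets) that were gonad-enriched or soma-enriched (y axis, 0 to 100%). The X chromosome has the lowest share of gonad-enriched genes (7.73%) and the highest share of soma-enriched genes (79.9%).

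The groups differed in both tissue and strain, so the comparison does not separate a gonad's RNA from effects of the *glp-4* mutation. The median log2 fold change of all tested genes was -1.50. The other scalings moved all genes by 0.08 (RLE), -0.15 (library size only) or -0.36 (upper quartile), so values within that distance of 0 have no firm direction. That distance is no upper bound on the error. These scalings take total RNA or the bulk of genes to be alike in the groups, while 12183 of 13101 genes differed. RNA per cell was not measured, and a larger shift would also change which genes near the fold minimum were called enriched.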

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

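Each headline result was recomputed under the alternatives that apply to its kind, and 375 of these 411 values left it as it was. A count was taken as unchanged within 1.5 times its main value, a wide margin. Counts taken as unchanged thus included 431 gonad-specific and 3216 soma-specific genes with an own-group minimum of 2 CPM, against 294 and 2259. The causes of changes were not tested except where the construction of a setting gives them. The gonad-enriched count was 2603 with a fold of at least 4, a narrower definition. The soma-enriched count was 4290 with the stricter filter, under which only 9324 genes were tested. The gonad-specific count was 181 with a detection limit of 0.5 CPM and 482 with 2 CPM. Restricted to specific genes, the odds ratio of X linkage was 0.867 and not significant (Fisher's exact test, p = 0.456). With an estimated correlation in camera, no list passed. Its adjusted p was 0.171 for stem cell, meiosis, P granule, small RNA, oocyte, chromatin, replication, intestine, collagen and innate immunity genes, 0.246 for neuron and pharynx genes, 0.300 for body wall muscle genes and 0.4535 for vitellogenins and histones. Lists with an estimated correlation under the preset 0.01 failed too, such as replication (-0.0289) and innate immunity (0.0092). High correlation within lists was thus not the reason in each case, and 2 residual degrees of freedom leave this test undecided. The test fry asks whether a list differs from no change, not from other genes as camera does, so its results are not the same result. Epidermis genes passed in several settings, with adjusted p of 0.0380 without a filter, 0.0447 with the stricter filter, 0.0123 with DESeq2, 0.0439 with the replicate block, 0.0493 on the authors' normalized table and 0.00580 with fry, and ranged from 0.0397 to 0.0583 with a library left out. Heat shock genes passed with DESeq2 (0.0406), on the authors' table (0.0334) and with fry (0.00227), somatic gonad genes with fry (0.00452), and spermatogenesis genes without a filter (0.0356) and with fry (0.00247). Coelomocyte genes had a median of opposite sign with the stricter filter (adjusted p = 0.620), and ribosomal protein genes without gonad replicate 2, in a range of 0.2405 to 0.652 over the libraries left out. Neither list passed in those settings. The stricter filter left only 3 of the 5 coelomocyte genes, of which 1 was soma-enriched against 3 before, and the median of those left was 0.664. For ribosomal protein genes the cause was not tested. List medians with many genes near 0 counts depended on the tool: on the authors' table, which adds 8 to the scaled count, they were -3.94 for innate immunity, -3.62 for neuron, -5.17 for pharynx and -5.75 for collagen genes, and with DESeq2, which tested 253 innate immunity genes, -5.46 for these. With a library left out, and the lone library of a group assumed to vary like the other group, counts ranged from 4049 to 4081 gonad-enriched, 6666 to 7325 soma-enriched, 311 to 336 gonad-specific and 2332 to 2366 soma-specific genes. A replicate block, for which replicate numbers are only a hint since differences within groups correlated by 0.206 across genes and 0.533 across 3957 genes with at least 10 CPM in every library, gave 4019 gonad-enriched and 6904 soma-enriched genes, of which 4017 and 6903 were shared. Of the 935 alternatives for 72 named genes, 914 kept the direction and whether the adjusted p was under 0.05, 11 lost it (*fln-1* and *rpl-3*), 9 gained it (*rps-1* and *rpl-6*) and 1 was reversed (*fln-1*, -0.0175 with upper-quartile factors).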

Other observations

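All of the tests in this part were chosen only after the results had been seen. Their intervals and p-values, here and in the paragraphs below, take genes as independent units, although genes of a list or family can vary together. They measure the spread between genes and not that between samples. Of 66 gene families named by a shared prefix and tested in both directions, 34 passed in one of them, and others, such as *rab* and *inx*, in neither. Nuclear pore genes (*npp*) were gonad-enriched in 24 of 26 cases (92.3%, Fisher's exact test, adjusted p = 1.89e-09 over the 66 families in both directions), led by *npp-9* (3.96 ± 0.18 log2, SE; 1745 CPM in gonads) and *npp-21* (3.16 ± 0.15). The *bath* genes, which encode BTB and MATH domain proteins, were gonad-enriched in 25 of 31 cases (80.6% against 30.7% of all other tested genes, adjusted p = 1.62e-07), for example *bath-42* (2.78 ± 0.15). Genes for SET-domain proteins (*set*) followed with 20 of 28 (adjusted p = 8.93e-05), among them *set-1* (3.04 ± 0.14) and *set-2* (355 CPM in gonads and 29.2 CPM in whole worms). Cell division cycle genes (*cdc*, 13 of 15, adjusted p = 8.93e-05), TATA-binding protein-associated factors (*taf*, 12 of 17, adjusted p = 4.19e-03) and Mediator subunits (*mdt*, 13 of 20, adjusted p = 7.23e-03) went the same way.

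Several families of receptors, neuropeptides and detoxifying enzymes were soma-enriched, while others of signalling and metabolism, such as *daf* (14 of 22, Fisher's exact test, adjusted p = 0.588) and *dhs* (20 of 29, adjusted p = 0.189), did not pass. Nuclear hormone receptor genes (*nhr*) were soma-enriched in 173 of 190 cases (91.1%, Fisher's exact test, adjusted p = 3.13e-28), for example *nhr-31* (-7.45 ± 0.27 log2, SE). All 29 FMRFamide-like peptide genes (*flp*, adjusted p = 1.49e-07) and 45 of 46 neuropeptide-like genes (*nlp*, adjusted p = 2.26e-10) were soma-enriched, including *nlp-40* (-6.84 ± 0.20). UDP-glucuronosyltransferase genes (*ugt*) were so in 57 of 60 cases (adjusted p = 2.32e-11), for example *ugt-22* (-8.33 ± 0.21), and cytochrome P450 genes (*cyp*) in 43 of 47 (adjusted p = 1.61e-07). The paralogs *cyp-31A2* (6.73 ± 0.18) and *cyp-31A3* (6.75 ± 0.20) were exceptions in gonads, with single values uncertain because their sequences are near-identical. F-box genes of the *fbxa* family were soma-enriched in 83 of 108 cases (adjusted p = 2.43e-06), yet 21 were gonad-enriched, among them *fbxa-215* (6.65 ± 0.18; 414 CPM in gonads and 4.12 CPM in whole worms).

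Gonad libraries kept more of the body wall muscle transcripts than of intestine or cuticle transcripts, relative to the levels in *glp-4* whole worms. Carry-over would come from the dissected N2 bodies, which are not among the samples. The readings below therefore assume that those bodies had the tissue proportions of *glp-4* worms, which was not tested. Among genes with at least 100 CPM in whole worms, the median residual was 2.10% for muscle and 0.137% for intestine, a ratio of 15.3 (bootstrap 95% interval 7.91 to 20.9, permutation p = 1e-05, the smallest possible), which argues against carry-over of whole-body RNA as the only source. The residual of cuticle collagens was 0.245 of that of muscle (0.164 to 0.489, permutation p = 1e-05), which argues against carry-over of body wall with its cuticle-forming cells as the whole source, although the epidermis genes *vab-10* and *ajm-1* kept 20.7% and 6.90%. Muscle genes expressed in the contractile sheath of the gonad may account for the excess over intestine, but this remained open and would not cover the neuron genes, at 3.03% (4 genes). Of 17 somatic gonad markers 4 were enriched in gonads and 9 in whole worms, and *glp-4* worms keep a somatic gonad as well, so those markers could not separate the sources.

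Transcripts of the germline lists were present in whole *glp-4* worms to different extents. The median was 0.849% of the gonad level for oocyte genes and 12.1% for chromatin regulators, a ratio of 14.2 (bootstrap 95% interval 9.0 to 20.5, permutation p = 0.0004). Oocyte genes and chromatin regulators had the lowest and the highest median of the germline lists, and the p-value does not account for that choice. Reads assigned to the wrong library, or RNA of whole gonads like those dissected, would bring a single share of every gonad transcript, so the ratio argues against either as the whole source. Such a share would also be limited by the genes kept least. These were *mex-1* at 0.217% (upper counting limit 0.29%), *perm-1* at 0.267% (0.344%) and *cey-2* at 0.273% (0.299%), although they were picked as the lowest of 1003 abundant gonad-enriched genes. High residuals were not particular to chromatin regulators, as stem cell and mitotic zone genes kept 11.9% (11 genes, quartiles 1.07 to 19.4) and small RNA pathway genes 10.6%. Expression of part of the germline genes in somatic cells or in remaining germ cells might explain the higher residuals, but the ratio of 14.2 is the observation itself, and this hypothesis was not tested separately.

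Gonad-specific genes were X-linked in 39 of 285 cases (13.7%), against 52 of 3124 other gonad-enriched genes (1.66%) with at least 5 CPM in both gonad libraries, an odds ratio of 9.37. Within 10 bins of gonad level the Mantel-Haenszel odds ratio was 4.66 (2.86 to 7.59). With each gene counted separately, the lower level of gonad-specific genes thus accounted for part of the excess but not for all. Of the 39 X-linked genes, led by *C04B4.2* and *ent-5* (97.4 and 90.4 CPM in gonads), 21 lay within 10 kb of another one (random median 2, permutation p = 1e-04, the smallest possible). With gonad-specific neighbours counted once the odds ratio was 7.90 (4.66 to 13.1), or 4.09 (2.39 to 7.0) within bins of level, which argues against extra calls from reads shared between neighbours as the whole cause. Merging neighbours among the other genes too left 1222 autosomal and 46 X-linked units of 3072 and 52 genes. The odds ratio was then 3.55 (2.07 to 5.98) without bins of level and 1.30 (0.74 to 2.26) within them. Merging alone thus did not remove the excess, whereas with merging and bins together no excess was detected. Its cause was left open, with no biological explanation tested.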
